A study of Homo sapiens with 8 samples.

How the data were processed

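RNA was measured on 8 2-colour oligonucleotide arrays (Agilent design 014850). Each array compared a Cy3-labelled untreated RNA with a Cy5-labelled RNA from human cells: osteoblasts or U2OS against mesenchymal stem cells (MSC) on 2 arrays, and a drug-treated culture against its own untreated control on 6 arrays. Dyes were never swapped, and each group had 1 array, so no drug and culture had a replicate. Per the file headers, the arrays lay on 2 slides of 4. The first slide held both arrays without drug and both MSC drug arrays, and the second held the osteoblast and U2OS drug arrays.

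Per the file headers, the deposited scanner files were made with Agilent Feature Extraction 9.5.3.1 and hold, per spot and dye, the mean signal and the median local background as raw intensity. They also hold a processed signal, an intensity that the authors' scanner software had background-subtracted, spatially detrended and dye-normalised. The deposited log10 ratio is that of processed Cy5 over processed Cy3, per the file headers. Per the labels' protocols, spike-in RNAs were added before amplification and the authors normalised with LOWESS and scaled the untreated channels to each other by quantiles. The submitters' processing notes name limma 3.6.9. The scale of the deposited value table was settled from its values: on every array they matched the log2 ratio of Cy5 over Cy3 after limma's loess without background correction, with slopes of 0.992 to 1 and correlations across probes of 0.991 to 1.

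From the raw intensities, 45015 features per array were read, of which 43376 spots of 41000 probes were not controls. Spots that the scanner software marked as outliers (77 to 156 per array) were set to missing. Background was corrected with limma 3.58.1 in R 4.3.3 (backgroundCorrect, normexp, offset 50), ratios were normalised within each array by loess, and spots of a probe were averaged. The median log2 ratio of all probes after loess lay between -0.01 and 0.02. The untreated Cy3 channels were quantile normalised for the comparison of cell types, which followed the labels' protocols. No probe was saturated. The scanner software called 76.5% to 82.2% of probes well above background in Cy3 and 91.1% to 94.9% in Cy5. The number of arrays limits the precision. In the scanner software's own quality figures, observed on known spike-in log ratios had slopes of 0.911 to 0.936, so its ratios were somewhat compressed.

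Probes were named through the RefSeq table of assembly GRCh38.p14, used for names only: 23434 by accession, 2317 by symbol and 1043 by an older symbol, while 14206 kept the name in the files. Probe coordinates are those of the files, on hg17 (NCBI35), and what the annotation of that build holds at each probe was not analysed here. Of several probes for a gene, the one with the highest mean intensity stood for it, giving 30866 genes. For 59 of the 153 pairs of a named gene and a comparison, other probes existed, and in 4 of these a probe had the opposite sign. A further 178 probes, for genes that can show a donor's sex or genotype, were left out of every step.

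A gene entered the comparison of cell types if it was well above background in at least 2 of the 8 untreated Cy3 channels (26538 genes), and the drug tests if it was so in at least 2 of the 12 channels of the drug arrays (29303 genes). Cell types were compared with lmFit and eBayes over the 8 untreated Cy3 channels (4 MSC, 2 osteoblast, 2 U2OS), sharing 1 estimate of the spread. Drug effects were tested on the log2 ratios of the 6 drug arrays, as the mean of each drug over the 3 cultures and as the difference of these means. A second model tested the difference between U2OS and the mean of the MSC and osteoblast cultures. In that model the spread came from MSC against osteoblast, and the lone U2OS array was assumed to vary like the others. P-values were adjusted by Benjamini-Hochberg, and a gene was called at an adjusted p under 0.05 and a change of at least 2-fold. Fold changes against a side that was not above background were computed against that array's floor and are given as lower bounds. A side counted as above background if any of its channels was well above background. The labels do not say that the channels of 1 cell type came from separate cultures, so p-values between cell types measure only the spread between these hybridisations, which may be technical.

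Lists of genes (22 lists, 392 of 398 members matched) were fixed before the data were examined, as were the tests, the rule for named genes and most alternatives. Lists were tested with camera at a preset correlation of 0.01 and with an estimated correlation, adjusted over the 22 lists, and members were counted both over all genes and adjusted over the list alone. For single drug arrays, a list's median was placed among those of 10000 random lists of the same size matched on expression, as a description. Named genes were the 10 largest rises and falls among called genes above background on both sides, with up to 5 lower bounds per direction. The other differences gave 5 per direction, and where nothing was called the 5 largest per direction with the same sign in every array. For each list, up to 4 called members or the 2 largest were taken. Named by rank were only names that the RefSeq table matched. DNMT1, DNMT3A, DNMT3B, CDKN1A and CDKN2A were always named.

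Genes low in U2OS were those at least 4-fold lower in U2OS than in MSC on the array that compared them directly, so that they were chosen and read out on different hybridisations. The 2 drugs share an untreated culture, and over genes the deviations of a culture's 5-Aza-CdR and TSA ratios from their drug means correlated at 0.21 in MSC, 0.06 in osteoblasts and 0.13 in U2OS, against at most 0.07 between cultures. The pairing comes from the labels, which give each culture both drugs.

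On simulated data with 100 genes changed by 1 and 100 by 2 on the log2 scale, the comparison of U2OS against MSC (26523 genes) called 99% of genes changed by 2 on the log2 scale with 2 false calls. The osteoblast comparison called 99% with 1 false call, and U2OS against osteoblast called 98% with none. Of 29288 genes, the 5-Aza-CdR mean called 90% and the TSA mean 95%, each with 1 false call, and TSA minus 5-Aza-CdR called 85% with 2. The difference of U2OS from the other cultures called 54% for 5-Aza-CdR with 1 false call and 43% for TSA with none, and 0% of genes changed by 1 in either. Of genes changed by 1, the other tests called 42%, 54% and 42% for the cell types in the same order, and 33%, 36% and 28% for the drugs. For the drug means and their difference, the simulated change was the same in every culture, and noise was independent between genes. The rates therefore do not cover drug responses that differ between cultures.

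Alternatives were no background correction, other filters, median centring, the scanner software's processed signals, the deposited value table, a dye term, blocks for culture or slide, each drug fitted alone, other limits for genes low in U2OS, and leaving out each channel or array. The slide could not be fitted as a block against MSC, since all untreated MSC channels lay on the first slide and all untreated osteoblast and U2OS channels on the second.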

Results

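Gene expression was measured in human mesenchymal stem cells (MSC) from adult bone marrow, in osteoblasts differentiated from such cells, and in U2OS, an established osteosarcoma cell line. Of 8 2-colour arrays, 1 compared osteoblasts with MSC, 1 compared U2OS with MSC, and 6 compared each of the 3 cultures after a drug with its own untreated control. The drugs were 5 µM 5-aza-2'-deoxycytidine (5-Aza-CdR) for 96 h, which inhibits DNA methyltransferases, and 300 nM trichostatin A (TSA) for 18 h, which inhibits histone deacetylases. Untreated RNA was always in the Cy3 channel, giving 4 channels of MSC, 2 of osteoblasts and 2 of U2OS, while no drug and culture had a replicate. Between 76.5% and 82.2% of probes were well above background in Cy3, and the number of arrays limits the precision. Values below are log2 differences with the standard error (SE) from limma and its adjusted p. Across probes, untreated channels of the same cell type correlated at 0.996 to 0.998, and MSC with U2OS channels at 0.88 to 0.895. Probes are not independent replicates.

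The comparison of U2OS with MSC asked how the tumour line differs from untransformed cells of the bone lineage. Expression of matrix genes was far lower in U2OS: COL1A2, a chain of type I collagen, was 974-fold lower (log2 -9.93, SE 0.113, adjusted p 3.3e-11), and DCN, the matrix proteoglycan decorin, was 573-fold lower (-9.16, SE 0.188, adjusted p 6.1e-10). The array that held both RNAs gave less, -6.19 for COL1A2 and -7.06 for DCN, and another COL1A2 probe differed by -6.78 between the channels. Some genes normally limited to the germ line were higher in U2OS (14 of 25 on the germline list, at an adjusted p of 0.33 with an estimated correlation). PRAME, a cancer-testis antigen, was 243-fold higher in U2OS (7.92, SE 0.602, adjusted p 2.2e-06), and XAGE1, of the same class, 391-fold higher (8.61, SE 0.949, adjusted p 3e-05), against 6.10 and 6.18 on the array that held both RNAs. Another PRAME probe differed by 4.91 between the channels. PRAME read 8.15 in the MSC channel that shared its array with U2OS RNA and 5.72 to 5.91 in the other MSC channels. In osteoblasts, where PRAME was not well above background, it read 5.90 to 5.91, so the 243-fold has a dim MSC side. Genes of cell division were also higher, among them TYMS, which makes thymidylate, 12.2-fold. These means rest on 4 MSC and 2 U2OS channels. On hg17, the probes lie on chromosome 7 at 93703294 to 93703353 for COL1A2, on chromosome 12 at 90042302 to 90042361 for DCN and on chromosome 22 at 21214760 to 21214819 for PRAME.

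Of 26538 genes tested, 5522 differed by at least 2-fold between U2OS and MSC, 2939 higher and 2583 lower in U2OS. Besides the cancer-testis antigens PAGE5 (7.37) and PAGE2 (7.25), the largest rises held DHRS2, a short-chain dehydrogenase (7.85, SE 1.21, adjusted p 3e-04), the chemokine CXCL14 (6.79), TNNT1, the slow muscle form of troponin T (6.35), ANXA10 (6.33), SUN3 (6.07), cyclin D2 (CCND2, 5.92) and the protease CTSV (5.85). PAGE5 read 8.64 in the MSC channel that shared its array with U2OS RNA and 6.145 to 6.481 in the other MSC channels. CXCL14 read 8.56 in that channel and 6.15 to 6.48 in the others. Neither gene was well above background in osteoblasts, where CXCL14 read 6.12 to 6.44. Some genes were not well above background in any MSC channel, so that U2OS was at least 79.3-fold higher for MAGEA1, at least 24-fold for the neurofilament gene NEFL, at least 18.9-fold for PAGE2B and at least 15-fold for CXADR. The largest falls also held CYP1B1, a cytochrome P450 (-9.18), CEMIP (-8.75), UCHL1, a ubiquitin hydrolase abundant in neurons (-8.57), SULF1 (-8.49), KRTAP1-5 (-8.10), CXCL12, the chemokine that marrow stroma makes (-8.00), STC2 (-7.74) and PRSS23 (-7.68), though other probes of CEMIP and CXCL12 read -3.16 and -1.78. The 2 U2OS channels differed for UCHL1, at 8.07 on the 5-Aza-CdR array and 6.57 on the TSA array. In the Cy3 channels, genes not well above background in U2OS were at least 785-fold (MARCKS), 443-fold (IGFBP3), 132-fold (PENK), 90.6-fold (NPR3) and 87.6-fold (MEST) lower there. On the array that held both RNAs these 5 read -7.99, -4.64, -4.89, -6.36 and -6.48, and other probes of IGFBP3 and NPR3 differed by -6.37 and -4.32 between the channels.

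The gene lists split along the same lines. All 20 extracellular matrix genes were lower in U2OS, FBN1 by -7.09, THBS2 by -6.89 and LUM by -6.06, and 23 of 24 cell cycle genes were higher, with MCM7 at 3.19 and CDK1 at 2.79. Camera gave each of these lists an adjusted p of 3.4e-11, and an adjusted p of 0.035 with an estimated correlation. Of 15 mesenchymal surface genes, 11 were lower (CD248 -7.27, ITGA11 -7.09, NT5E -6.78; adjusted p 2.6e-06, and 0.035 with an estimated correlation). Contractile genes were lower in 14 of 15 cases, among them ACTA2 (-7.45) and TAGLN (-4.69), and 14 of 25 genes whose promoters are often methylated in cancer were lower, among them DKK1, a Wnt antagonist (-6.42), TFPI2 (at least 63.6-fold) and TIMP3 (-5.45). Their adjusted p values were 2.3e-06 and 0.00011, and 0.077 and 0.053 with an estimated correlation. Of 18 bone matrix genes, 9 were lower (COL1A1 -4.23, TNFRSF11B, which encodes osteoprotegerin, -3.97, SPARC -1.85) and 1 was higher (adjusted p 0.0024, and 0.053 with an estimated correlation).

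Further lists passed the preset test only. Germline genes were higher in U2OS in 14 of 25 cases (adjusted p 0.0029, and adjusted p = 0.33 with an estimated correlation). Histone genes were higher in 8 of 10 cases and lower in 1 (H1-2 4.97, H2BC12 4.11; 0.0029, and 0.081 with an estimated correlation). Of 20 cholesterol synthesis genes, 9 were higher and 1 lower (HSD17B7 2.22, ACAT2 1.96; 0.0026, and 0.053 with an estimated correlation). Chromatin enzymes were higher in 4 and lower in 1 of 21 cases (EED 1.70, HDAC4 -1.43; 0.0011, and 0.053 with an estimated correlation). Interferon genes were lower in 9 of 22 cases (IFI27 -2.36, IRF7 -2.32; 0.007, and 0.33 with an estimated correlation), and 2 of 10 metallothioneins were higher (MT1M 1.94; 0.01, and 0.44 with an estimated correlation). The remaining 10 lists did not pass, with members going both ways: higher and lower calls numbered 2 and 1 for adipocyte, 1 and 2 for chondrocyte, 3 and 1 for epithelial, 4 and 2 for neuronal, 2 and 1 for p53 target, 3 and 7 for HOX, 1 and 2 for NF-kappaB and 1 and 5 for stress genes. Blood cell markers were lower in 2 cases and endothelial markers in 1. Single members still differed widely, such as KRT8 (4.29) against KRT19 (-6.17), HOXB9 (3.64) and IL6 (-4.37). Counts adjusted over the list alone were equal to those over all genes for every list in the 3 comparisons of cell types.

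The test was limma over the untreated channels. All MSC channels lay on 1 slide and all U2OS and osteoblast channels on the other, but on the array that held both RNAs, 85% of the 5522 genes differed by at least 2-fold in the same direction. The MSC channel on that array read several U2OS genes higher than the other MSC channels did, with PRAME at 8.15 against 5.72 to 5.91. Many of the largest differences, in both directions, were smaller on that array, with DHRS2 at 4.06 and STC2 at -4.12, so their size depended on the array. Its U2OS Cy5 channel read COL1A2 at 11.41 and IGFBP3 at 10.93, where the U2OS Cy3 channels read 6.73 to 7.01 and 6.42 to 6.63. PRAME read 14.35 in that Cy5 channel and 14.3 to 14.4 in Cy3. Cy5 was not quantile normalised with the Cy3 channels, and the cause of the higher Cy5 readings was not tested. Without the MSC channels on the osteoblast and U2OS arrays, an alternative chosen after seeing the data, DHRS2 differed by 8.98, PAGE5 by 7.96 and TNNT1 by 6.95.

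**Figure D1:**
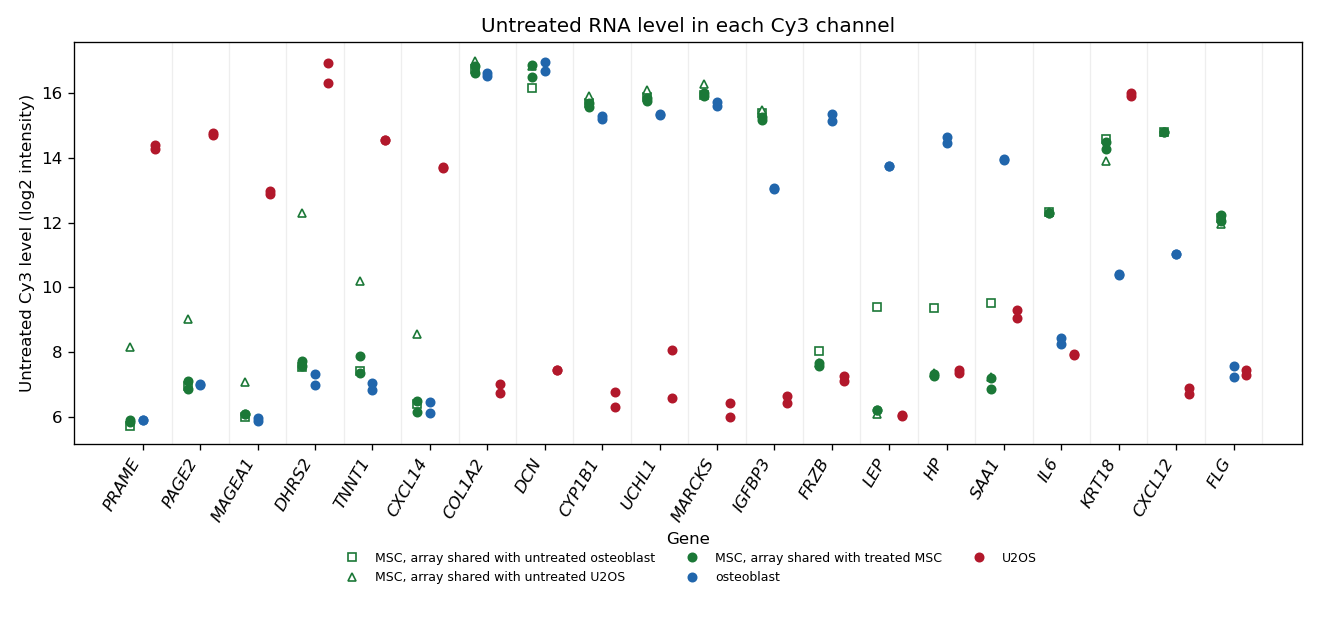
Normalised log2 intensity of named genes in the untreated Cy3 channels of MSC (4 channels), osteoblasts (2) and U2OS (2), where each point is 1 channel. COL1A2 lay at 16.6 to 17 in MSC and at 6.73 to 7.01 in U2OS, while PRAME lay at 14.3 to 14.4 in U2OS and at 8.15 in the MSC channel that shared its array with U2OS RNA.

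The comparison of osteoblasts with MSC asked how the differentiated cells differ from MSC. Differences of donor or culture conditions were not separated from differentiation. FRZB, a secreted Wnt antagonist of skeletal tissue, was 185-fold higher in osteoblasts (7.53, SE 0.13, adjusted p 1.3e-09, 2 osteoblast and 4 MSC channels). LEP, the adipose hormone leptin, was 110-fold higher (6.78, SE 0.824, adjusted p 0.00022), and the acute phase genes HP (6.72) and SAA1 (6.23) were higher too. LEP read 9.38 in the MSC channel that shared its array with osteoblast RNA and 6.10 to 6.21 in the other MSC channels. In U2OS, where LEP was not well above background, it read 6.02 to 6.05, so the 110-fold has a dim MSC side. The bone genes OMD (osteomodulin, at least 14.1-fold), SPP1 (osteopontin, 2.99) and ALPL (alkaline phosphatase, 1.24) were the only 3 of 18 bone matrix genes called, all higher. LYPD1 (-4.72, SE 0.0579, adjusted p 3.8e-10), the inflammatory cytokine IL6 (-3.97) and the chemokine CXCL12 (-3.77) were lower, with other probes of LYPD1 and CXCL12 at -1.97 and -1.36. The FRZB probe lies on chromosome 2 at 183524387 to 183524446 of hg17.

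In all, 1073 of 26538 genes differed between osteoblasts and MSC, 601 higher and 472 lower in osteoblasts. Further large rises were those of ZIM2 (5.38), CXCL1 (5.26), SAA2 (5.24), TNFAIP8L3 (4.99) and MGP, an inhibitor of calcification (4.75). F7 rose by 5.30 on its brightest probe while another probe for it read 0.04, and other probes of SAA2 and TNFAIP8L3 read 0.92 and 1.23. Against MSC channels not well above background, osteoblasts were at least 8.28-fold higher for MCTP1, at least 5.72-fold for CCDC68 and at least 5.35-fold for KLF15, although another probe of KLF15 read -0.03. Lower genes held FLG (-4.70), PENK (-4.11), SCRG1 (-4.10), the keratins KRT19 (-4.10) and KRT18 (-3.92), PSAT1, an enzyme of serine synthesis (-3.93), and the imprinted gene MEST (-3.91). Another KRT18 probe read -0.74. Not well above background in osteoblasts were MAP3K7CL (at least 9.73-fold lower), GAP43 (2.63-fold), CADM1 (2.35-fold), EPGN (2.27-fold) and LRRC17 (2.22-fold), with another CADM1 probe at -0.20.

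Among the lists, 6 of 10 adipocyte genes were higher in osteoblasts, including PPARG, the regulator of fat cell formation (2.94), CFD (2.93) and LPL (at least 3.77-fold; camera adjusted p 3.9e-05, and 0.097 with an estimated correlation). Metallothioneins, which bind zinc and copper, were higher in 8 of 10 cases (MT1B 1.48, camera adjusted p 1.4e-05, and 0.29 with an estimated correlation, which was 0.72). Interferon genes were shifted up with 2 of 22 called (IFI6 1.69, MX1 1.24; 2.9e-06, and 0.18 with an estimated correlation), as were histone genes with 4 of 10 called (0.0026, and 0.14 with an estimated correlation). Stress genes were lower in 5 of 13 cases and higher in 1 (ASNS -3.16 and TRIB3 -2.55, both induced by amino acid shortage, against TXNIP 2.12; 0.00046, and 0.097 with an estimated correlation). Extracellular matrix genes were lower in 4 and higher in 1 of 20 cases (LUM -1.66, MMP2 -1.49; 0.0084, and 0.22 with an estimated correlation). No cell cycle gene was called, and the median of the 24 was -0.20 (0.011, and 0.28 with an estimated correlation). None of 20 cholesterol genes was called either (0.0094, and 0.14 with an estimated correlation), while 2 of 8 epithelial genes were lower (0.029, and 0.18 with an estimated correlation). Bone matrix as a list had a median of -0.10 but a mean of 0.47, and did not pass (adjusted p 0.36). Nor did the other lists, where higher and lower calls numbered 2 and 3 for mesenchymal surface genes (LEPR 3.84), 4 and 2 for NF-kappaB genes (ICAM1 2.62), 2 and 1 for chondrocyte genes (COMP 2.99), 1 and 3 for contractile genes (INHBA -2.32), 1 and 2 for neuronal genes, and 2 and 2 for genes with promoters methylated in cancer (SFRP1 1.96).

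On the array that held both RNAs, 85.6% of the 1073 genes differed by at least 2-fold in the same direction. The MSC channel on that array read LEP at 9.38 and the other 3 at 6.10 to 6.21, and the array itself gave LEP 4.26, HP 5.19, SAA1 4.48 and FRZB 7.38. Without the MSC channels on the osteoblast and U2OS arrays, LEP differed by 7.54, SAA1 by 6.91, ZIM2 by 6.32, F7 by 5.97 and TNFAIP8L3 by 5.65.

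Between U2OS and osteoblasts, which lay on the same slide, the tumour line was again lower in matrix genes and higher in several cancer-testis antigens. COL1A2 was lower by -9.71, DCN by -9.39 and SULF1 by -8.76, and COMP, a cartilage and tendon matrix protein, by -8.46. DHRS2 was 713-fold higher in U2OS (9.48, SE 1.4, adjusted p 0.00023), and PRAME, PAGE5 and CXCL14 were at least 220-fold, 212-fold and 142-fold higher. With 2 channels on each side, 6157 of 26538 genes differed, 3226 higher and 2931 lower in U2OS.

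Other high genes in U2OS against osteoblasts were PAGE2 (7.73), TNNT1 (7.61), MAGEA12 (6.50), S100A2 (6.20), MAGEA2B (6.16), CCND2 (6.11), CTSV (6.07), SUN3 (6.06), the keratin KRT80 (6.01), ANXA10 (at least 138-fold) and MAGEA1 (at least 82.9-fold). Other low genes were CYP1B1 (-8.70), the phosphatase DUSP23 (-8.66), IGFBP2 (-8.63), PRSS23 (-8.21) and CLEC3B (-8.12), and MARCKS (at least 607-fold), NPR3 (181-fold), LEP (163-fold), IRS2 (105-fold) and IGFBP3 (91.3-fold) were not well above background in U2OS. FGF7P6 read -8.30, with another probe for it at 0.89, and another IRS2 probe read -0.51. Other probes of PRAME, KRT80, COL1A2, NPR3 and IGFBP3 read 5.35, 2.68, -6.90, -5.36 and -4.23. All 20 matrix genes were lower and 23 of 24 cell cycle genes higher (adjusted p 2.2e-11 each), and 11 of 15 mesenchymal surface genes were lower (8.8e-06). All 3 lists had an adjusted p of 0.034 with an estimated correlation. Bone matrix genes were lower in 9 of 18 cases (SPP1 -4.12; 0.00031) and genes with promoters methylated in cancer in 13 of 25 (5.3e-05), both at an adjusted p of 0.048 with an estimated correlation. Interferon genes were lower in 12 of 22 cases (MX1 -3.08; 8.1e-06, and 0.12 with an estimated correlation), contractile genes in 9 of 15 with 1 higher (0.00023, and 0.12 likewise), and adipocyte genes in 4 of 10 with 1 higher (0.027, and 0.12 likewise). Germline genes were higher in 14 of 25 cases (0.0044, and 0.33 with an estimated correlation), histone genes in 8 of 10 with 1 lower (0.0044, and 0.1 likewise), cholesterol genes in 9 of 20 with 2 lower (0.0092, and 0.095 likewise) and chromatin enzymes in 5 of 21 with 2 lower (0.014, and 0.1 likewise). None of the 10 metallothioneins was called.

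The DNA methyltransferases, which 5-Aza-CdR inhibits, and 2 cell cycle inhibitors were named whatever their result. DNMT3B, a methyltransferase that sets up new DNA methylation, was higher in U2OS than in MSC (2.34, SE 0.0842, adjusted p 1.6e-08) and than in osteoblasts (2.94). DNMT1, which maintains methylation, was 1.95-fold higher in U2OS than in MSC and DNMT3A 1.42-fold, both short of 2-fold. CDKN2A, which encodes the inhibitor p16, was lower in U2OS than in MSC (-2.12, SE 0.0639, adjusted p 5.6e-09), and CDKN1A, which encodes p21, differed by -0.88. Between osteoblasts and MSC none of the 5 reached 2-fold, with values from -0.76 for CDKN1A to 0.11 for CDKN2A. None of the 5 was called for either drug. CDKN1A averaged 0.93 with 5-Aza-CdR (adjusted p 0.23), reading 1.01 in MSC, 0.28 in osteoblasts and 1.50 in U2OS. CDKN2A averaged 0.50 (adjusted p 0.27), reading 0.37 in MSC, 0.12 in osteoblasts and 1.03 in U2OS.

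The 5-Aza-CdR arrays asked which genes respond to this inhibitor of DNA methyltransferases in each culture. DNA methylation itself was not measured on these arrays. In U2OS, several genes normally limited to the germ line read far higher after the drug, with VCX3A 149-fold, VCX 117-fold and GAGE12F 31.7-fold higher. UCHL1 and the Wnt antagonist DKK1, both low in untreated U2OS, read 59.7-fold and 55-fold higher. The size of such ratios depended on the untreated channel, as the 2 untreated U2OS channels had an SD of 1.06 for UCHL1, 1.14 for VCX, 0.89 for VCX3A and 0.24 for DKK1. MSC also read germline genes higher, with SPANXA1 at 3.58 and VCX3A at 2.54, and read the cell division genes PBK (-1.72), RRM2 (-1.69), SPC25 (-1.62) and NUF2 (-1.61) lower. In osteoblasts few genes moved, S100P, a calcium-binding protein, being the highest at 1.27. S100P also read 2.44 in MSC and 3.22 in U2OS.

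At least 2-fold higher and lower with 5-Aza-CdR were 149 and 85 genes in MSC, 4 and 0 in osteoblasts, and 1063 and 620 in U2OS. With median centring of the arrays in place of loess these numbers were 327 and 58, 84 and 18, and 1839 and 334, so the balance of higher to lower genes depended on the scaling. Of genes at least 2-fold higher, 46 were shared by MSC and U2OS, where independent lists would share 5.41. Across genes, the 5-Aza-CdR ratios correlated at 0.53 between MSC and osteoblasts, 0.35 between MSC and U2OS and 0.22 between osteoblasts and U2OS, and genes are not independent replicates. Other genes high in MSC were PI16 (2.49) and STMN3 (2.17), and HAS2, which makes hyaluronan, read -1.65. In osteoblasts IL18 and LY6K read 1.10 each, KRT18 0.97 and TRMT1L -0.82. In U2OS the lysyl oxidase LOXL1 (-3.05), LHPP (-2.78), BNC2 (-2.67), PKIB (-2.66) and CXCL14 (-2.64) were lowest.

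By lists, germline genes had a median of 0.95 in U2OS with 14 of 29 at least 2-fold higher, and of 0.24 in MSC with 5 of 26, both above all 10000 matched random lists. The median was 0.04 in osteoblasts (percentile 72.9). Cell cycle genes had medians of -0.81 in MSC, where 9 of 24 were at least 2-fold lower, -0.53 in U2OS and -0.01 in osteoblasts (percentile 30.2). The p53 targets had medians of 0.41, 0.49 and 0.07 in MSC, U2OS and osteoblasts. In U2OS, cholesterol synthesis genes (-0.69) and histone genes (-0.70) were low and NF-kappaB genes (0.65) high. Cholesterol genes also read low in MSC (-0.167, percentile 0.4) and osteoblasts (-0.0887, percentile 0.69). NF-kappaB genes also read high in MSC (0.295, percentile 100) and osteoblasts (0.0963, percentile 98.4), while histone genes read 0.21 in MSC and 0.0505 in osteoblasts. The interferon list in osteoblasts had a median of 0.14 (percentile 99.98) with 0 of 22 genes at 2-fold. Its median was 0.159 in MSC (percentile 99.9) and 0.148 in U2OS (percentile 95.7).

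Averaged over the 3 cultures, no gene was called with 5-Aza-CdR: limma called 0 of 29303, with 4704 at an unadjusted p under 0.05 and a smallest adjusted p of 0.078. With median centring it called 156 (139 higher, 17 lower). The largest means of 1 sign in every culture were VCX3A 3.26, S100P 2.31 (SE 0.392, adjusted p 0.12), RRAD 2.14, FMR1NB 2.05 and SPANXA1 2.02, and the nuclear lamina gene LMNB1 -1.27, the receptor AXL -1.13, LOXL1 -1.12, TMEM106C -1.08 and LHPP -1.07. The shared sign can be nominal: in osteoblasts VCX3A read 0.02 and LHPP -0.01, against 7.22 and -2.78 in U2OS, while S100P read 1.27 in osteoblasts. Camera found cell cycle genes shifted down (median -0.45, adjusted p 1.2e-05), as cholesterol genes were (-0.33, 0.00015), and germline genes (0.47, 3.5e-05), p53 targets (0.32, 0.00018) and NF-kappaB genes (0.42, 0.035) shifted up. With an estimated correlation each of these lists had an adjusted p of 0.56. With median centring the test of the cholesterol list pointed up, at a median of -0.01 and an adjusted p of 0.9. No member of any list was called, over all genes or adjusted over the list alone.

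The TSA arrays asked which genes respond to inhibition of histone deacetylases. Averaged over the cultures, AREG, the growth factor amphiregulin, rose by 2.67 (SE 0.53, adjusted p 0.036), and read 2.82 in MSC, 3.04 in osteoblasts and 2.17 in U2OS. TUBB2B, a tubulin of neurons, rose by 2.66 (SE 0.414, adjusted p 0.024). Of 10 metallothioneins 7 rose, led by MT2A at 1.44, while the list had an adjusted p of 0.9 with an estimated correlation. TNFRSF11B, the decoy receptor that restrains osteoclasts, fell by 2.44 (SE 0.484, adjusted p 0.036), and EPC2, an enhancer of polycomb homologue, fell by 1.63 (SE 0.119, adjusted p 0.015) with similar values of -1.61, -1.74 and -1.54 in MSC, osteoblasts and U2OS.

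Of 29303 genes, 383 changed with TSA on average over 3 arrays, 231 up and 152 down, with 9257 at an unadjusted p under 0.05. Median centring gave 905 up and 103 down. Other rises were those of ROPN1L (2.47), FBXL16 (2.17), the Notch target HEY1 (2.16), BIRC3, an inhibitor of apoptosis (2.13), the neuronal kinesin KIF5C (2.12), AP1S3 (2.09) and the neurofilament gene NEFH (2.06). DACT3 rose by 2.50, with another probe for it at 0.17. WNT16 was at least 2-fold, CLXN at least 1.94-fold and SLAIN1 at least 1.74-fold higher. Falls were those of ZNF469 (-2.47), CARD6 (-2.17), HOXB2 (-2.00), TNFRSF12A (-1.99), the deacetylase HDAC7 (-1.66), the unfolded protein response factor XBP1 (-1.63) and GBP3 (-1.59). GINS3 fell by 1.79, with another probe at -0.36, and other probes of HOXB2 and CLXN read -0.93 and 0.56.

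In single cultures, 659 genes in MSC and 858 in osteoblasts were at least 2-fold higher with TSA and 612 and 833 lower, against 233 and 100 in U2OS. With median centring the higher and lower genes were 1463 and 296 in MSC, 1958 and 436 in osteoblasts, and 614 and 70 in U2OS. MSC and osteoblasts shared 436 of the higher genes, where independent lists would share 19.3, and 51 were higher in all 3 cultures. The TSA ratios correlated across genes at 0.80 between MSC and osteoblasts, 0.46 between MSC and U2OS and 0.47 between osteoblasts and U2OS. MIAT (3.27), CXCL1 (3.26) and NFE2L3 (3.23) led in MSC, with B3GNT9 (-2.57) among the lowest. F11R, a tight junction protein (3.59), was among the highest in osteoblasts, and FGF7, a growth factor for epithelium, read -4.07 there. In U2OS, MXD1 (2.58), HEY1 (2.46), SNAI1 (2.37) and the immediate early gene FOS (2.29) were highest, and CXCL14 (-2.25), EDN2 (-1.90), PGBD2 (-1.80) and EPC1 (-1.79) lowest.

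Camera passed 5 lists with TSA, each at an adjusted p of 0.9 with an estimated correlation. Of the metallothioneins, 9 passed when adjusted over the list alone (camera adjusted p 1.9e-06). All 10 were at least 2-fold higher in MSC and in osteoblasts, where their medians were 1.25 and 1.69, against 1 in U2OS with a median of 0.74. The estimated correlation between these genes was 0.92, so they are not separate results. Whether their probes tell the transcripts apart was not tested. Of 22 neuronal genes, 1 rose over all genes and 4 adjusted over the list alone (MAPT, the gene of tau, 1.74; 0.00021). The cell cycle list was shifted down with 1 of 24 called (AURKA -1.08; 5.1e-06), as were p53 targets with 0 of 18 called (median -0.34; 0.0075). Of 20 matrix genes, TIMP3 rose (1.43) while the list was shifted down at a median of -0.32 (0.0075). Adjusted over the list alone, 0 matrix genes passed, and with median centring the median was 0.14. The other lists did not pass, and members called in them were HOXA13 (1.14), HOXB2, HOXC9 (-1.27), HDAC7, UHRF1 (-1.36), RASSF1 (-1.03), IFIT3 (-1.13), TNFRSF11B and the heat shock gene HSPA1A (1.72). TIMP3, which rose, is also on the list of promoters often methylated in cancer, where RASSF1 fell. Adjusted over the list alone, 2 stress genes passed higher and 1 lower. Interferon genes had a median of -0.49 in osteoblasts.

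The 383 calls came from the joint limma fit of both drugs. Without U2OS with TSA the count was 1047, without osteoblasts with 5-Aza-CdR it was 70, and it was 0 without MSC with 5-Aza-CdR, without MSC with TSA, without osteoblasts with TSA, or with TSA fitted alone. In these 4 fits 7961, 5929, 5827 and 8581 genes had an unadjusted p under 0.05 in limma. With the slide as a block 191 were called.

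**Figure D2:**
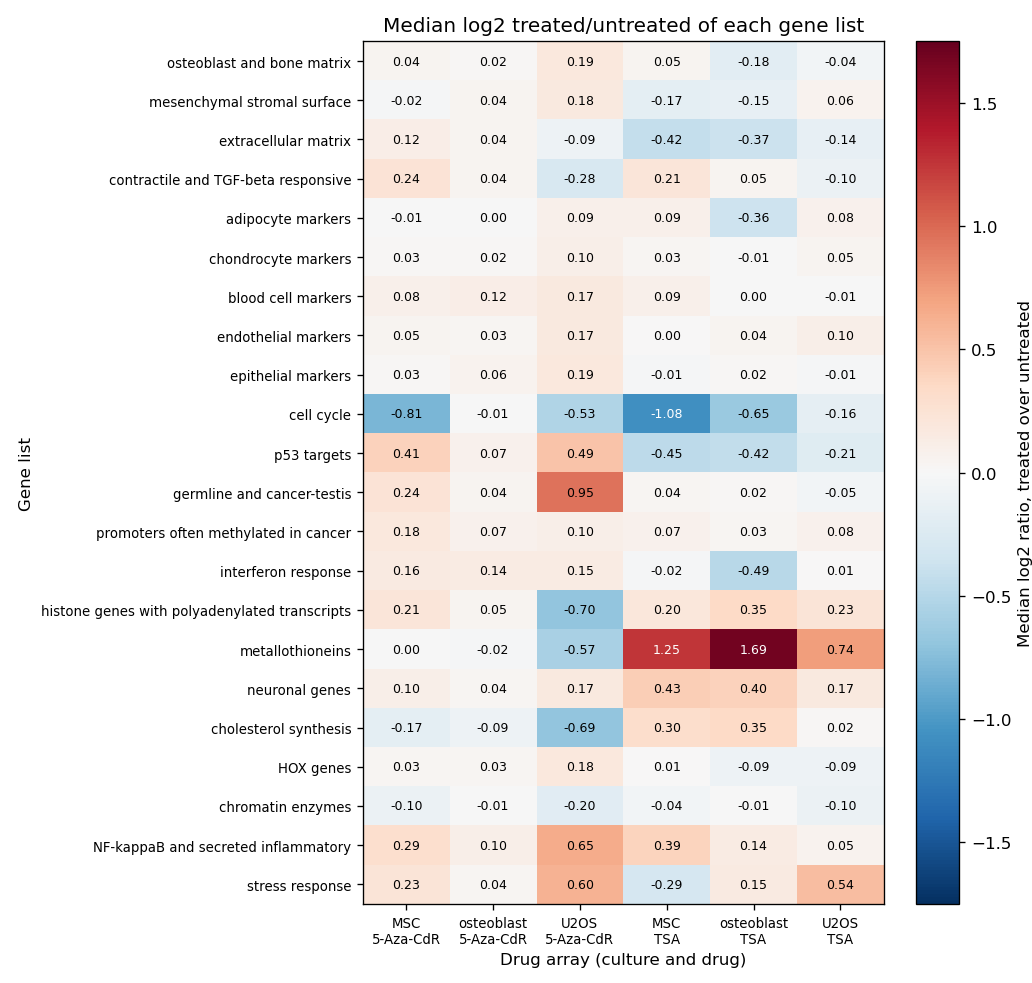
Median log2 ratio of treated over untreated RNA for the genes of each list (vertical) on each of the 6 drug arrays (horizontal), with the value in each cell and 1 array per column. Germline genes stand out with 5-Aza-CdR in U2OS (0.95), and metallothioneins with TSA in MSC (1.25) and osteoblasts (1.69).

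Set against each other, TSA and 5-Aza-CdR differed most in metallothioneins, which lay higher with TSA (median 1.44), and in p53 targets, which lay lower (median -0.65). Each had a camera adjusted p of 0.47 with an estimated correlation. TUBB2B differed by 2.46, CPA4 by 2.23, DACT3 by 2.10 and FBXL16 by 2.08. The germline genes VCX3A (-3.85), VCX (-3.68) and GCNA (-2.77), the keratin KRT7 (-2.56) and LY6K (-2.27) were at the other end, while other probes of DACT3 and LY6K read 0.13 and -0.11. None of these genes passed: limma called 0 of 29303, with 4159 at an unadjusted p under 0.05 and a smallest adjusted p of 0.13. Adjusted over the list alone, 9 of 10 metallothioneins were higher and 3 of 18 p53 targets and 3 of 34 HOX genes lower. Camera gave adjusted p values of 4.4e-10 for metallothioneins, 8.5e-09 for p53 targets, 2.2e-05 for cholesterol genes (0.49), 0.00013 for germline genes (-0.59), 0.0015 for HOX genes (-0.14), 0.0077 for matrix, interferon and neuronal genes, and 0.037 for histone genes. With an estimated correlation these lists had adjusted p values of 0.47 to 0.53. The 2 drugs were given at different doses and for different times. With culture as the replicate block limma again called 0 genes, with 4842 at an unadjusted p under 0.05. Within the second slide alone, an alternative chosen after seeing the data, the matrix list had a median of -0.09 and a camera adjusted p of 0.096. Without U2OS with TSA, 486 genes were called.

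Whether the tumour line responds differently was tested as the change in U2OS minus the mean change in MSC and osteoblasts. U2OS had 1 array per drug and the spread came from MSC against osteoblasts, so U2OS was assumed to vary like them and its response was not separated from variation between arrays. With 5-Aza-CdR, 11 of 28 germline genes lay higher on the U2OS array (adjusted p 0.64 for the list with an estimated correlation), among them TKTL1 (4.19) and the spermatogenesis genes MAEL (3.61), STK31 (3.58) and SYCP3 (3.27). UCHL1 lay higher by 5.84 (SE 0.185, adjusted p 0.003), DKK1 by 5.84, VCX3A by 5.94, the collagenase MMP1 by 4.30 and the phosphatase DUSP6 by 4.23. Other probes of MMP1 and BNC2 read -0.01 and -0.86. LOXL1 (-2.89), EDN2 (-2.83), the CXCL12 receptor ACKR3 (-2.70), LHPP (-2.57) and BNC2 (-2.49) were at the other end.

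In all, limma called 1111 of 29301 genes for 5-Aza-CdR, 750 higher and 361 lower on the U2OS array. The split was 1157 and 323 with median centring and 240 and 56 with the scanner software's processed signals. Camera passed 5 lists, each at an adjusted p of 0.64 with an estimated correlation. Adjusted over the list alone, 12 germline genes passed (median 0.73, camera adjusted p 8.4e-08). Cholesterol genes were lower in 2 of 20 cases (DHCR7 -1.46, LSS -1.02; 1.1e-05), histone genes in 3 of 10 (H2BC12 -1.72; 0.0032), and metallothioneins in none (median -0.53; 0.0051). NF-kappaB genes were higher in 5 of 18 cases (CCL20 2.85, MMP3 2.55; 0.019). Of matrix genes 4 of 20 were lower, and 5 adjusted over the list alone, as were 4 histone genes. Here 1 U2OS array stood against 2 others, and without MSC with 5-Aza-CdR 184 genes were called and without osteoblasts with 5-Aza-CdR 144.

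With TSA, CPA4, a carboxypeptidase, read 3.14 in MSC, 3.31 in osteoblasts and 0.05 in U2OS (difference -3.17, SE 0.124, adjusted p 0.045). PLK2 (-2.77), PHLDA1 (-2.53), the desaturase SCD5 (-2.51) and PRSS2 (-2.34) also changed less or in the other direction in U2OS, although other probes of PHLDA1 and SCD5 read -0.49 and -0.17. The changes of IER5L (2.68), EFS (2.57), ACOX2 (2.40) and SLC16A5 (2.30) lay higher in U2OS, as did that of B3GNT9 (2.64), for which another probe read 0.16. B3GNT9 did not rise in U2OS, where it read 0.04, against -2.57 in MSC and -2.62 in osteoblasts. Of 29303 genes 219 differed, 95 higher and 124 lower, with 5577 at an unadjusted p under 0.05. Metallothioneins were shifted less in U2OS (median -0.72; camera adjusted p 2.9e-06), cell cycle genes were lowered less (0.70; 0.00048) and cholesterol genes lay lower (-0.34; 0.00048), each at an adjusted p of 0.94 with an estimated correlation. Adjusted over the list alone, 3 metallothioneins and 3 cholesterol genes passed. The 219 calls lay just under the threshold, with a smallest adjusted p of 0.045, and there were 0 without MSC with 5-Aza-CdR or without osteoblasts with 5-Aza-CdR (4272 with an unadjusted p under 0.05 in limma), but 1079 without MSC with TSA and 747 without osteoblasts with TSA. The count was also 0 with the slide as a block, without background correction, with the processed signals, with the deposited value table and with genes well above background in every channel, where 5610, 5785, 4897, 5654 and 4606 had an unadjusted p under 0.05.

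The last comparison asked whether genes lower in the tumour line than in MSC, some of them still well expressed there, read higher with either drug. On the direct array, 925 genes were at least 4-fold lower in U2OS than in MSC. With 5-Aza-CdR, 174 of them (18.8%) read at least 2-fold higher in U2OS, led by UCHL1 (59.7-fold), DKK1 (55-fold), TFPI2, an inhibitor of serine proteases (at least 36.8-fold), MARCKS (at least 15.5-fold) and the keratin KRT19 (4.05), and 47 read at least 2-fold lower. With TSA 29 did (3.14%), led by the transcription factors MXD1 (2.58) and FOS (2.29), and 12 read lower. UCHL1 with TSA read 0.12 and DKK1 0.07.

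Random lists matched on untreated intensity in U2OS gave 3.14% higher genes with 5-Aza-CdR on average and 5.73% at most, and 0.757% and 2.05% with TSA. The median log2 ratio of the 925 genes was 0.21 with 5-Aza-CdR, where the highest of 10000 matched lists reached 0.05, and 0.01 with TSA (percentile 10.6). With median centring the TSA median was -0.21. The median difference of the 2 drugs in U2OS was 0.19, against at most 0.04 in matched lists. The same genes had medians of -0.03 and -0.02 with 5-Aza-CdR in MSC and osteoblasts, and of -0.27 and -0.28 with TSA. Further genes higher with 5-Aza-CdR were DUSP6 (3.89), SPINT2 (3.75), KRT7 (3.71), DUSP23 (3.65) and ANGPTL4 (3.36). With TSA they were PPP1R3C (1.86), NEFH (1.85), BAMBI (1.72), TXNIP (1.59), PXK (1.47), NLRP1 (1.45), TIPARP (1.39) and ZFP36 (1.35). Of 9 such genes on the list of promoters often methylated in cancer, 5 read at least 2-fold higher with 5-Aza-CdR, as did 2 of 20 matrix genes and 0 of 9 mesenchymal surface genes. Both drugs were read on 1 U2OS array each, so these values describe those arrays.

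**Figure D3:**
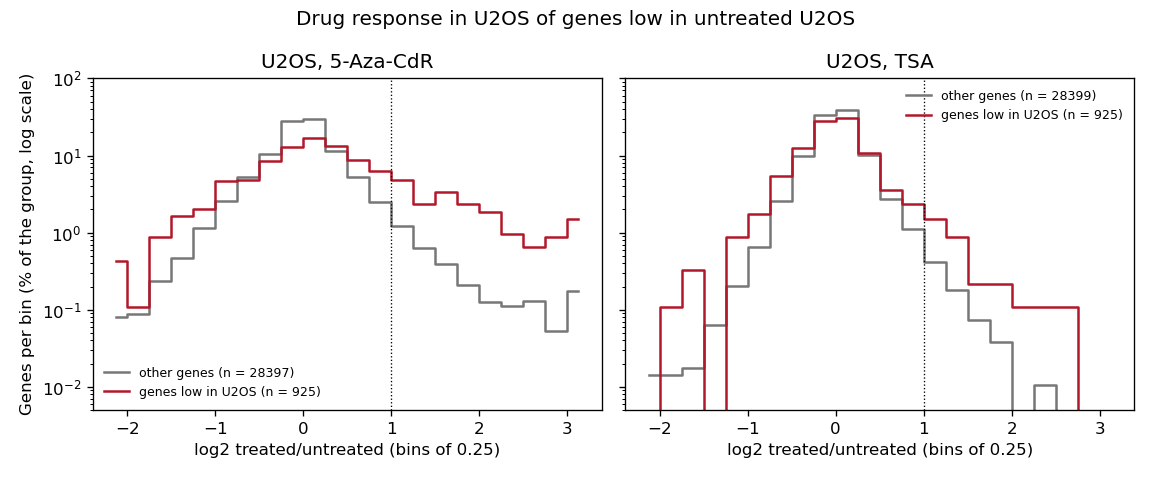
Share of genes by log2 ratio of treated over untreated U2OS RNA, for 5-Aza-CdR and for TSA, in bins of 0.25 with a log vertical axis and the end bins holding all values beyond, for the 925 genes low in U2OS and for the other genes. To the right of the dotted line at 2-fold lie 174 of the 925 genes with 5-Aza-CdR and 29 with TSA.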

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

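The tests of compressed ratios and of untreated RNA in both channels, and the fit without the MSC channels of the osteoblast and U2OS arrays, were chosen after the results were seen.

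Of 67 genes named in the comparisons of cell types, 22 had 1 of the 4 untreated MSC channels far from the other 3, with a gap over the whole range at or above Dixon's critical value of 0.829, where chance passes about 1 in 20 groups. The channel on its own lay highest for 20 genes and lowest for 2, and it was on the osteoblast or U2OS array for 21 of the 22. For genes high or low in U2OS the values were PRAME 0.922, DHRS2 0.959, PAGE5 0.865, PAGE2 0.887, CXCL14 0.862, SUN3 0.925, CCND2 0.889, MAGEA1 0.902, MAGEA12 0.934, MAGEA2B 0.939, KRT80 0.854, IGFBP2 0.892, COMP 0.864 and NPR3 0.911. For genes high in osteoblasts the values were LEP 0.966, HP 0.952, SAA1 0.855, ZIM2 0.962, F7 0.937, SAA2 0.931, TNFAIP8L3 0.892 and MGP 0.829. Genes were then taken with a log2 Cy5 level of at least 12 that lay at least 32-fold above the other MSC channels. For these, the MSC channel of the U2OS array was raised by a median of 1.44 (27 of 36 genes by 2-fold, a median of 2.14% of the Cy5 signal). On the osteoblast array the median was 2.50 (12 of 13 genes, 6.26%), and on the array without that Cy5 RNA the same genes shifted by -0.03 and -0.06. At an 8-fold limit the medians were smaller, 0.573 on the U2OS array (35 of 117 genes by 2-fold) and 1.15 on the osteoblast array (15 of 29). Without those MSC channels limma called 5698 genes between U2OS and MSC, 5465 of them among the 5522 of all channels, and 1104 between osteoblasts and MSC, 1055 of them among the 1073.

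With 1 U2OS array per drug, the differences of U2OS from the other cultures were not separated from variation between arrays. Results that differed between U2OS and the mean of MSC and osteoblasts by an interaction test in limma were 1111 genes with 5-Aza-CdR, the named ones being VCX3A (5.94), UCHL1 (5.84), DKK1 (5.84), MMP1 (4.30), DUSP6 (4.23), LOXL1 (-2.89), EDN2 (-2.83), ACKR3 (-2.70), LHPP (-2.57) and BNC2 (-2.49). With TSA they were 219 genes, the named ones being IER5L (2.68), B3GNT9 (2.64), EFS (2.57), ACOX2 (2.40), SLC16A5 (2.30), CPA4 (-3.17), PLK2 (-2.77), PHLDA1 (-2.53), SCD5 (-2.51) and PRSS2 (-2.34). Lists that differed in camera with 5-Aza-CdR were germline (0.735), histone (-0.903), metallothionein (-0.531), cholesterol (-0.563) and NF-kappaB genes (0.256), each at an adjusted p of 0.64 with an estimated correlation. With TSA they were cell cycle (0.697), metallothionein (-0.72) and cholesterol genes (-0.342), each at an adjusted p of 0.94 with an estimated correlation.

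Genes low in U2OS read higher there after 5-Aza-CdR, at a median of 0.206. Dim probes would raise random lists matched on untreated intensity as much, and the highest of 10000 reached 0.054. A return toward the mean cannot be judged from these lists, which were not chosen for a low reading. The genes were chosen on another hybridisation, but the labels do not say that its U2OS RNA came from a separate culture. A dye bias of the treated channel would act on both drug arrays, but the difference of the 5-Aza-CdR and TSA ratios had a median of 0.188, against at most 0.0435. Whether loss of promoter methylation or a later effect of the drug raised these genes stays open, since DNA methylation was not measured. Of 27 genes with promoters often methylated in cancer, 7 read at least 2-fold higher in U2OS and 3 lower, at a list percentile of 88.4. Of all 28934 genes above background on that array, 1063 read at least 2-fold higher. The list does not show which promoters are methylated in U2OS.

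With 5-Aza-CdR, 4 genes changed by 2-fold in osteoblasts against 1683 in U2OS, and in osteoblasts the number was 102 with median centring and 354 with processed signals. Compressed ratios on that array were weighed by the spike-in controls, whose slope of 0.93 was 1.02 times the lowest slope of the other arrays, 0.911. The scanner software computed that slope, so it cannot speak to compression by the background offset and loess behind the 4 genes. Untreated RNA in both channels was weighed by correlation across genes. The ratios correlated at 0.53 with 5-Aza-CdR in MSC and at most at 0.16 with the arrays without drug, a difference of 0.38. They correlated at 0.22 with 5-Aza-CdR in U2OS, and with TSA at 0.24 in MSC, 0.21 in osteoblasts and 0.24 in U2OS. Since dyes were never swapped, a dye bias shared by arrays could also link them, so this test cannot decide. Slower division of the osteoblasts, which could limit a drug that acts in DNA replication, was tested by the cell cycle list, at a median of -0.198 between untreated osteoblasts and MSC (21 of 24 genes lower, -0.187 on the direct array), and stays open at an adjusted p of 0.28 with an estimated correlation.

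The slide was weighed for the comparisons with MSC, because slide and cell type coincide in the untreated channels. On the array that held both RNAs, 85% of the genes called between U2OS and MSC and 85.6% of those called between osteoblasts and MSC differed by 2-fold in the same direction. The slopes of the direct ratios on the channel differences were 0.909 and 0.906. A slide effect of smaller size stays open, since no MSC channel lay on the second slide.

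TSA against 5-Aza-CdR called 0 genes in limma, so all 10 ways of dividing the 6 drug arrays into 3 and 3 necessarily called as many. That count therefore cannot decide anything. At an unadjusted p under 0.05 in limma there were 4159 genes, against at most 2604 in the other divisions, and 10 are too few to set a threshold.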

How the results depend on the processing

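Alternatives chosen after seeing the data were the slide as a block for the drug tests, the second slide alone for TSA minus 5-Aza-CdR, untreated channels of both dyes with a dye term, and the fit without the MSC channels of the osteoblast and U2OS arrays. Counts for the cell types stayed within 1.5 times under every alternative run for them, at 4703 to 5988 for U2OS against MSC, 900 to 1111 for osteoblasts against MSC and 5227 to 6524 for U2OS against osteoblasts. The drug counts did not, and the cause was not tested. With 5-Aza-CdR the mean over cultures gave 156 genes with median centring and 11 with a dye term. With TSA it gave 1008 with median centring, 735 with processed signals, 587 with a dye term, 191 with the slide as a block and 0 with the drug fitted alone, where the spread rests on 3 arrays, as well as 368 with culture as a random block. The difference of U2OS from the other cultures gave 296 with 5-Aza-CdR and processed signals, and 0 with TSA without background correction, with genes well above background in every channel, with processed signals, with the authors' value table and with the slide as a block. Genes changed by 2-fold on single arrays with median centring were 385 (MSC, 5-Aza-CdR), 102 (osteoblasts, 5-Aza-CdR) and 684 (U2OS, TSA). With processed signals they were 706, 354 and 3367 with 5-Aza-CdR and 2765, 3530 and 1124 with TSA in MSC, osteoblasts and U2OS. Genes low in U2OS had TSA medians of 0.00498 at a 2-fold limit, 0.00414 without background correction and -0.21 with median centring, and 5-Aza-CdR medians of 0.0794 to 0.356.

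Signs that turned were DNMT3A with 5-Aza-CdR at 0.194 with median centring and 0.0459 with a dye term, DNMT3B with 5-Aza-CdR at 0.00834 and CDKN2A with TSA at -0.0287 with a dye term, the cholesterol list with 5-Aza-CdR, whose test pointed up at a median of -0.00687, and the matrix list with TSA at 0.143, both with median centring. With 1 array or channel left out, where a lone array is assumed to vary like the others, the ranges were -0.0655 to 0.0163 for DNMT3A with 5-Aza-CdR, -0.153 to 0.419 for DNMT3B with TSA, 0 to 1047 for TSA, 0 to 0 for 5-Aza-CdR, 0 to 486 for TSA minus 5-Aza-CdR, 144 to 1406 and 0 to 1079 for U2OS minus the others with 5-Aza-CdR and with TSA, 5484 to 5645 for U2OS against MSC, 1068 to 1111 for osteoblasts against MSC and 6144 to 6235 for U2OS against osteoblasts.

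With culture as the replicate block, limma called 0 genes for TSA minus 5-Aza-CdR (4842 with an unadjusted p under 0.05), as without it, and no list changed its call. For named genes, 1055 values with 1 array or channel left out and 1075 under other alternatives kept sign and side of the threshold, 118 and 122 lost the call, 3 and 5 gained it and 2 and 4 turned. Of the losses, 153 were for TSA and 71 for TSA in U2OS minus the others. For lists, 410 and 363 kept both and 8 and 19 lost the call, 10 of the losses being for TSA minus 5-Aza-CdR and 7 for 5-Aza-CdR. Not run were a separate-channel fit with an intraspot correlation for the cell types, because that correlation could not be estimated, and the slide as a block against MSC, because slide and cell type coincide. The fit of untreated channels of both dyes, which was run, took the array as a random block at an estimated correlation of 0.5. Processed signals and the authors' value table, which were planned for the drugs, were not run for the cell types. Between 76.5% and 82.2% of probes were well above background in Cy3, which limits the genes that can be compared.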

Other observations

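The values in this part were read after the results were seen and were not tested between cultures.

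With TSA, NF-kappaB and secreted inflammatory genes had a median of 0.39 in MSC, where 5 of 18 read at least 2-fold higher, of 0.14 in osteoblasts and of 0.05 in U2OS. CXCL1 read 3.26 in MSC, -1.37 in osteoblasts and 0.09 in U2OS. Interferon genes with TSA had a median of -0.49 in osteoblasts, where 7 of 23 read at least 2-fold lower and 2 higher, against -0.02 in MSC and 0.01 in U2OS. Adipocyte genes, 6 of 10 of which were higher in osteoblasts than in MSC, had a median of -0.36 with TSA in osteoblasts, with 3 of 10 at least 2-fold lower, and of 0.09 in MSC. FGF7 read -1.57 in MSC, -4.07 in osteoblasts and -0.11 in U2OS.

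Stress response genes in U2OS had medians of 0.605 with 5-Aza-CdR and 0.54 with TSA, and 5 and 4 of 13 read at least 2-fold higher, while with TSA in MSC the median was -0.29 and 4 were lower. CXCL14, high in U2OS, read -2.64 with 5-Aza-CdR and -2.25 with TSA there.

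Contractile genes had a median of 0.24 with 5-Aza-CdR in MSC (percentile 99.87) and of -0.28 in U2OS (percentile 2.72). NFE2L3 read 3.23 with TSA in MSC and 2.80 in osteoblasts but 0.09 in U2OS, where it read 3.83 with 5-Aza-CdR.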
